A study of Mus musculus with 7 samples.

How the data were processed

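The 7 libraries are bulk RNA sequencing of mouse primary articular chondrocytes treated for 24 h with vehicle (n = 2), TGFβ1 (n = 2) or BMP2 (n = 3). The deposited file holds 1 count per gene name and library, and a gene length, for 52459 gene names; per the submitters' processing notes, cutadapt, STAR 2.4.2a, Subread, featureCounts and DESeq2 were used with the mm10 build, with no role or order stated. The annotation, the strand setting and the handling of multi-mapped reads are not given in the sources used here. The values were whole numbers whose totals differed between libraries, from 6747997 to 18047765, and were treated as raw counts that had not been normalised. The gene length column deposited by the authors was not used here.

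Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups given (13367 genes), libraries were scaled by TMM, and 1 quasi-likelihood fit with a coefficient per group was made over all 7 libraries, which leaves 4 residual degrees of freedom. The common biological coefficient of variation was 0.133. The contrasts were TGFβ1 against vehicle, BMP2 against vehicle and BMP2 against TGFβ1, each tested 2-sided with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. With 2 or 3 libraries per group and 2 vehicle libraries shared by both comparisons, small changes can go unseen. Standard errors are those of the fitted log2 fold change, and CPM were computed with the TMM-scaled library sizes.

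The design, the tests, the gene lists and the rule for the genes named were fixed before the data were examined. The rule takes, for each comparison, (a) the 6 largest rises and 6 largest falls among genes past the threshold with a mean log2 CPM of at least 2, separate CPM ranges and a named symbol; (b) up to 4 members of each list with the smallest p; (c) a fixed set that includes Id1, Smad7, Sox9, Col2a1, Acan, Prg4, Col10a1 and Mmp13; and (d) the 4 genes of opposite direction for the 2 ligands with the largest difference between them. It gives 115, 105 and 107 genes for the 3 comparisons, 182 in all. The text names all of (a), (c) and (d) except for 2 genes, which are not reported here, and a part of (b), chosen for brevity with values in view; all 327 pairs of gene and comparison were put through the alternatives. A few further list members and 2 library-composition genes are named with their values in view; every list member was put through the same alternatives.

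The lists cover the TGFβ-SMAD2/3 and BMP-SMAD1/5 responses, cartilage matrix and the SOX9 programme, the superficial zone, hypertrophy, osteoblasts, fibrous matrix, actin and contractile genes, matrix proteases and inhibitors, inflammatory mediators, glycolysis, oxidative phosphorylation, the cell cycle, the TGFβ superfamily, the Wnt, Notch and FGF pathways, proteoglycan and hyaluronan synthesis, and markers of leukocytes, neutrophils, osteoclasts, endothelium, erythroid cells, fibroblasts, adipocytes, skeletal muscle and pericytes. Lists share members (Sp7, Alpl and Smad7, for example). Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 26 lists with a tested gene, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Fry called 18, 15 and 23 of the 26 lists in the 3 comparisons, and only camera is given per list. The erythroid list had 0 tested genes. Members were counted after adjustment over all genes and over the list alone. Snorc is in the file under an older symbol and was counted in the cartilage list only after the list results had been seen; without it camera called 8 lists for TGFβ1 against vehicle rather than 5, with fibrous matrix and oxidative phosphorylation at adjusted p = 0.0479 each, and at 0.521 and 0.505 with an estimated correlation.

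Gene names were matched to the mouse annotation of the mm10 build for position, exon overlap, length and GC content of the principal transcript: 45707 names as given, 2401 with another separator in place of a hyphen and 192 through a RefSeq synonym, with 4159 unmatched. Of the tested genes 13228 (98.96%) had a length and a GC content. A principal transcript can be shorter than the isoform the cells express. The length offset was made per library from lowess trends of log2 CPM (prior count 1) on transcript length (span 0.15) and then GC content (span 0.3), with 3 iterations, and entered into the edgeR fit, where the common coefficient of variation was 0.120. It was chosen after the length trend had been seen, as were its settings, the choice of principal transcripts, the restriction to transcripts of at least 2000 nt and the fits that combine the offset with a library left out.

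The alternatives fixed at the start were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in edgeR, no filter on low counts, only the libraries of the 2 groups compared, the replicate number as a term in the fit, an added minimum absolute log2 fold change of 1, and each library left out in turn. The settings meant for normalised values did not apply, since the file holds counts. The overlap of both responses was set beside the counts for independent lists and beside 20 simulated draws of unchanged groups that share the vehicle libraries. Floors for genes at 0 in a group are 3 counts over the group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and plots.

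The gene fits against vehicle, and the list tests for BMP2 against vehicle, were run on simulated counts; BMP2 against TGFβ1 was not tested in this way. For TGFβ1 against vehicle, edgeR on 12699 simulated genes recovered 59.8% of those changed by 1 on the log2 scale and 89.6% of those changed by 2, and called 0.14% of the unchanged; for BMP2 against vehicle it recovered 68.1% and 94.6% and called 0.14%. DESeq2 on 13367 genes recovered 54% and 83% for TGFβ1 and 53% and 87% for BMP2. The length and GC trend that the offset fit had estimated was also put into the simulated counts. There edgeR called 23.34% of unchanged genes for TGFβ1 against vehicle (12693 genes run), and 0.20% with the length offset (12594 genes run). Since the trend put in was of the kind the offset removes, this cannot show that the offset removes the real trend in full. For BMP2 against vehicle, camera recovered 10 of 10 changed lists and called 0 of 10 unchanged ones with either correlation, and fry recovered 10 and called 1 (12731 genes run).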

Results

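Gene expression was measured by bulk RNA sequencing in primary mouse articular chondrocytes from the femoral head, cultured for 24 h with vehicle, with TGFβ1 at 5 ng/ml or with BMP2 at 100 ng/ml. TGFβ1 and BMP2 are ligands of the same family that signal mainly through SMAD2/3 and through SMAD1/5. The data hold 7 libraries: 2 with vehicle (replicates 1 and 2), 2 with TGFβ1 (replicates 1 and 3) and 3 with BMP2 (replicates 1, 2 and 3). The labels do not say whether the replicates are separate animals, separate cultures or repeated libraries of 1 culture, so every p-value measures the spread between these samples, which may be technical. The total count was 6885056 and 7387051 in the vehicle libraries, 18047765 and 16271793 in the TGFβ1 libraries, and 10686885, 6747997 and 9796199 in the BMP2 libraries. Of 52459 gene names, 13367 had enough counts to be tested. A gene is said to have risen, fallen or changed where its adjusted p in edgeR was under 0.05. Fold changes are on the log2 scale with their standard error (SE), and levels are CPM, counts scaled to the effective library size, as mean ± SD over the libraries of a group.

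The TGFβ1 libraries stood apart from the other 5 in their gene composition. Ribosomal protein genes (Rpl and Rps) held 6.79% ± 0.0707 of the counts with TGFβ1 (SD, n = 2), 1.14% ± 0.0396 with vehicle (n = 2) and 1.25% ± 0.177 with BMP2 (n = 3). CT010467.1, which the annotation classes as ribosomal RNA, held 5.24% ± 0.0735, 15.4% ± 1.16 and 14.98% ± 1.06 in the same order, and Lars2 held 3.95% ± 0.658, 9.71% ± 0.624 and 9.49% ± 0.254; both genes were chosen after their values were seen. Mitochondrially encoded genes held 2.88% ± 0.143 of the counts with TGFβ1, 3.21% ± 0.0636 with vehicle and 3.50% ± 0.181 with BMP2. The first principal component carried 83.09% of the variance and separated the TGFβ1 libraries from the rest, and the second, with 9.06%, separated BMP2 from vehicle. Across genes, the correlation of log2 CPM (after adding 1) was 0.990 between both TGFβ1 libraries, 0.829 to 0.864 between a TGFβ1 library and any other, and 0.967 to 0.993 among the BMP2 and vehicle libraries. BMP2 replicate 1 stood apart from the other BMP2 libraries: chi-square per gene, which is near 1 for counting error alone and grows with depth, was 1.88 between BMP2 replicates 2 and 3, and 14.4 and 18.6 between each of these and replicate 1, beside 4.73 between the vehicle and 42.9 between the TGFβ1 libraries. The third component, with 3.14% of the variance, had BMP2 replicate 1 at −23.4 and BMP2 replicates 2 and 3 at 13.9 and 11.4.

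Transcript length moved with the TGFβ1 effect. In the 701 genes with a principal transcript of at most 750 nt the median fold change of TGFβ1 against vehicle was 2.82, in 2940 genes above 2000 and up to 3000 nt it was 0.02, and in 987 genes above 7000 nt it was −0.56. The same medians for BMP2 against vehicle lay between −0.08 and 0.08. The TGFβ1 libraries also differed from each other by length: the median of log2 CPM (after adding 1) in replicate 1 minus replicate 3 was 0.30 above 750 and up to 1000 nt, 0.35 in the next longer group of genes and −0.10 above 7000 nt. Between the vehicle libraries such medians lay between −0.04 and 0.05, between BMP2 replicates 2 and 3 between −0.04 and 0.01, and between BMP2 replicate 1 and either other BMP2 library between −0.08 and 0.10. Against the mean of the vehicle libraries, the medians of the 3 BMP2 libraries lay between −0.11 and 0.07 in every length group. Across genes, Spearman's rho of the fold change with transcript length was −0.424 for TGFβ1, −0.0696 for BMP2 and 0.389 for BMP2 against TGFβ1; genes are not independent replicates. Changes of named genes with transcripts of at most 1000 nt in any comparison with TGFβ1 are therefore given with their value in a fit that carries an offset for transcript length and GC content (the length offset), an alternative chosen after the trend had been seen. The treatment and this difference between libraries coincide, so a TGFβ1 effect that itself depends on length would also be removed by the offset. Any difference between the libraries that follows neither length nor GC content would stay in each comparison with TGFβ1. It could not be told from an effect of the ligand.

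**Figure D1:**
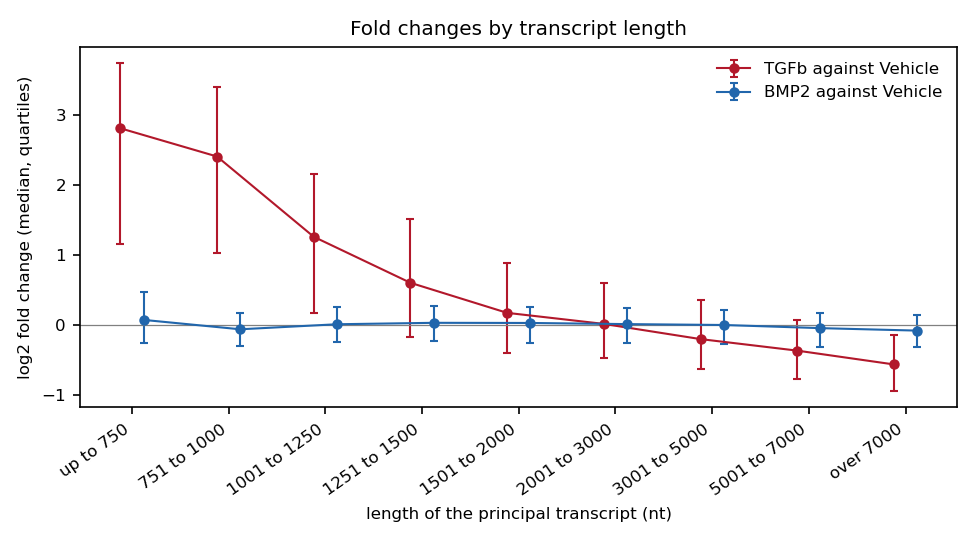
Median (points) and quartiles (bars) of the log2 fold change over genes grouped by the length of the principal transcript, for TGFβ1 against vehicle and BMP2 against vehicle. The TGFβ1 medians fall from 2.82 in the shortest group to −0.56 in the longest, and the BMP2 medians stay between −0.08 and 0.08.

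The first comparison asks what TGFβ1 does to the transcripts of articular chondrocytes. Prg4, which encodes the joint lubricant lubricin (chromosome 1, 150449412 to 150466165, mm10), rose from 382 ± 44.2 to 6151 ± 196 CPM (n = 2 and 2), a log2 fold change of 4.01 (SE 0.18, adjusted p = 2.61e-08). Pmepa1, a SMAD2/3 target that restrains TGFβ signalling, rose from 22.5 ± 0.1 to 737 ± 47.6 CPM, and the matrix protein gene Cilp from 4.94 ± 1.31 to 136 ± 0.335 CPM, by 5.03 and 4.77. Sox9, the transcription factor that drives cartilage matrix genes, fell from 542 ± 20.1 to 206 ± 30.4 CPM (log2 fold change −1.40, SE 0.16, adjusted p = 4.51e-05). Ihh, a signal made by prehypertrophic chondrocytes, fell from 2.81 ± 0.757 to 0.226 ± 0.112 CPM (−3.56, SE 0.64). In all, 4067 genes rose and 3450 fell. With the length offset 3348 rose and 3177 fell; of the 4018 genes with a length that had risen, 2875 still rose, 1002 no longer passed the threshold and 141 fell.

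The largest rises among genes with a mean log2 CPM of at least 2 were those of R3hdml (8.50), the cytokine gene Il11 (8.22), Fxyd2 (8.20), the cytidine deaminase gene Cda (7.88), the extracellular matrix gene Adamtsl2 (7.33) and M1ap (7.26). R3hdml, Fxyd2 and Cda have transcripts of 1094, 632 and 846 nt, and with the length offset their rises were 6.94, 5.28 and 5.46, against 8.02 for Il11, 7.24 for Adamtsl2 and 7.01 for M1ap. R3hdml differed between its replicates, at 1957 ± 716 CPM. Il11 stood at 0.134 and 0.478 CPM in the vehicle libraries, so the size of its rise rests on few counts there. The largest falls were those of the immunoglobulin gene Igkc (−5.67), Nov (−4.53), Myoc (−4.46), the imprinted gene Peg10 (−4.42), the adhesion receptor gene Adgrf5 (−4.41) and Thsd4 (−4.35). Each of these 6 fell with the length offset as well, with fold changes of −8.38, −4.43, −4.69, −3.93, −3.82 and −4.19. Igkc stood at 0.147 and 0.153 CPM in the TGFβ1 libraries, beside 7.62 and 8.85 CPM with vehicle, so the size of its fall rests on few counts.

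Of 20 genes of the TGFβ-SMAD2/3 response, 15 rose and 2 fell, the same numbers adjusted over the list alone and with the length offset. The list stood above other genes by camera at adjusted p = 4.50e-05, and adjusted p = 0.331 with an estimated correlation. Ltbp2, which encodes a matrix protein of the latent TGFβ binding family, rose by 4.31 (SE 0.16). Timp1 rose by 4.20, and by 1.99 with the length offset (883 nt). Smad7, an inhibitor of both pathways, rose by 0.70 (SE 0.14). Of the 18 genes of the BMP-SMAD1/5 response 11 fell and 3 rose, with 12 down and 4 up adjusted over the list alone, and 12 down and 1 up with the length offset. Camera gave the list adjusted p = 0.00852, and adjusted p = 0.331 with an estimated correlation. Hey1 (−3.34), Smad9 (−2.65) and Dlx5 (−2.58) were among those that fell. The 3 that rose were Smad7, Id2 (0.65) and Id3 (1.17). Neither Id2 nor Id3 passed without TGFβ1 replicate 1 (0.34 and 0.31), without vehicle replicate 1 (0.63 and 1.12), without vehicle replicate 2 (0.63 and 1.17) or with the length offset (−0.05 and 0.14). Id1, a direct BMP target, stood at 246 CPM in TGFβ1 replicate 1 and 68.3 CPM in TGFβ1 replicate 3, beside 76.9 and 74.4 CPM with vehicle. Its fold change of 1.06 did not pass the threshold (adjusted p = 0.0531). It was 1.71 without TGFβ1 replicate 3 and −0.14 without TGFβ1 replicate 1, and passed at 1.01 without the filter on low counts. With the length offset Id1 (934 nt) passed in the other direction, with a fall of −1.17 (adjusted p = 0.0087).

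Among 14 superficial-zone genes 7 rose with TGFβ1, among them Prg4, Cilp, Clu and Gdf5, and Vit fell, the same numbers adjusted over the list alone, with 7 up and 2 down with the length offset. Camera gave adjusted p = 0.0420, and adjusted p = 0.331 with an estimated correlation. Clu rose by 2.27 (SE 0.18), and Gdf5 by 3.95 (SE 0.51), although 40.3% of the exon bases of Gdf5 overlap a gene on the other strand and the strand setting is not given in the sources used here. Gdf5 stood at 0.134 and 1.67 CPM with vehicle, beside 13.7 and 15.7 CPM with TGFβ1. The size of its rise thus depends on low and differing vehicle values. Of 24 genes of cartilage matrix and the SOX9 programme 13 fell and 5 rose (14 and 5 adjusted over the list alone; 12 and 4 with the length offset), which camera did not separate from other genes (adjusted p = 0.0678, and adjusted p = 0.488 with an estimated correlation). The falls included Matn1 (−2.99, SE 0.15), Col9a1 (−1.75, SE 0.13) and the aggrecan gene Acan (−0.88, SE 0.13, and −0.56 with the length offset), and the rises Chad (2.88) and Cilp2 (1.96). Without Snorc, which was added to the list after the list results had been seen, the cartilage list passed at adjusted p = 0.0362, and adjusted p = 0.425 with an estimated correlation. Col2a1, the main cartilage collagen gene, was not shown to change (−0.26, SE 0.15, adjusted p = 0.146), and was past the threshold without TGFβ1 replicate 3 (−0.39) and without the filter on low counts (−0.31). Of 17 genes of chondrocyte hypertrophy 8 fell and 3 rose, the same adjusted over the list alone and 9 and 3 with the length offset (camera adjusted p = 0.0678, and 0.331 with an estimated correlation). Panx3 (−3.44, SE 0.15) and Mef2c (−1.21) fell, and Ank and Enpp1, both of pyrophosphate metabolism, rose by 1.87 and 1.26. Col10a1 (−0.31) and Mmp13 (−0.27) did not pass the threshold, and did without TGFβ1 replicate 3, at −0.48 and −0.42; Col10a1 also passed without BMP2 replicate 1, at −0.31. Of 9 tested osteoblast genes Smpd3 (−4.09), Alpl (−1.42), Runx2 and Sp7 fell and Col1a1 (1.15) rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0678, and 0.331 with an estimated correlation), with 6 down and 1 up with the length offset.

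Of 19 fibrous matrix genes 12 rose with TGFβ1 and 2 fell (Thbs1, and Tnc at −0.63, which did not pass with the length offset at −0.28), with 13 and 2 adjusted over the list alone and 13 and 1 with the length offset; camera gave adjusted p = 0.0548, and adjusted p = 0.521 with an estimated correlation. The lysyl oxidase gene Lox rose from 149 ± 12.4 to 1361 ± 150 CPM, by 3.19 (SE 0.15), elastin (Eln) by 4.30 (SE 0.25) and Col3a1 by 1.35 (SE 0.14). Of 15 actin and contractile genes 8 rose and 0 fell, the same adjusted over the list alone and 7 and 0 with the length offset (camera adjusted p = 0.120, and 0.488 with an estimated correlation), among them Tpm1 (1.52) and Actn1 (1.07). The 4 tested genes of the pericyte and smooth muscle list rose too (camera adjusted p = 0.171). Among 16 matrix proteases and inhibitors 8 rose and 4 fell, the same adjusted over the list alone and 7 and 3 with the length offset, with no separation by camera (adjusted p = 0.821). Adamts9 fell by 2.82 and Htra1 and Mmp14 rose by 1.89 and 1.35.

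Of 12 inflammatory mediators 10 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0250, and adjusted p = 0.331 with an estimated correlation), and with the length offset 6 rose and 1 fell. Lif rose by 4.25 and Ptgs2 by 1.42, and with the offset by 4.32 and 1.84. Saa3, with a transcript of 555 nt, rose by 3.28 (SE 0.27), but by 0.41 with the length offset, which did not pass. Of 18 genes of glycolysis 13 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.331 with an estimated correlation), with 11 up and 2 down with the length offset. The lactate transporter gene Slc16a3 rose by 2.74 (SE 0.14), and by 2.75 with the offset. Pkm rose by 1.76 (SE 0.13) and shares 15.3% of its exon bases with another gene. Oxidative phosphorylation was called in parts only: 8 of 21 genes rose and 2 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0548, and 0.505 with an estimated correlation), and with the length offset 6 rose and 5 fell. Cox4i1, of 765 nt, rose by 4.13 (SE 0.14), and by 1.45 with the offset.

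The second comparison asks what BMP2 does. Ihh (chromosome 1, 74945315 to 74951672) rose from 2.81 ± 0.757 to 44.2 ± 13.1 CPM (n = 2 and 3), a log2 fold change of 3.99 (SE 0.30, adjusted p = 4.09e-05). The BMP antagonist gene Nog (chromosome 11, 89300638 to 89302332) rose from 8.71 ± 1.49 to 106 ± 8.89 CPM, by 3.61 (SE 0.19, adjusted p = 6.15e-06). Hey1 rose by 3.09 and Smad7 by 2.32, and the hypertrophic collagen gene Col10a1 rose from 498 ± 5.2 to 1088 ± 25.6 CPM (1.13, SE 0.13). Prg4 fell from 382 ± 44.2 to 190 ± 24.6 CPM (−1.01, SE 0.14, adjusted p = 0.00128), and the collagenase gene Mmp13 from 329 ± 11.2 to 89.0 ± 8.77 CPM (−1.89, SE 0.13). In all, 713 genes rose and 822 fell, and with the length offset 906 and 838. The total of 1535 was 671 without vehicle replicate 1, 557 without vehicle replicate 2 and 981 without BMP2 replicate 3; rises and falls were 276 and 395, 245 and 312, and 472 and 509 in the same order.

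The largest rises were those of the homeobox gene Dlx2 (4.33), Ihh, Spon2 (3.93), the prostaglandin synthase gene Ptgs2 (3.67), Nog and Fabp7 (3.52). The largest falls were those of the proton pump subunit gene Atp6v0a4 (−4.52), Podnl1 (−3.51), Palmd (−3.23), Angpt1 (−2.99), the enkephalin precursor gene Penk (−2.90) and Sfrp4 (−2.81). Angpt1 and Penk share 14.2% and 14.3% of their exon bases with genes on the other strand. Penk was the most abundant of the 6 that fell, from 495 ± 37.7 to 66.4 ± 9.34 CPM.

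Of the 18 BMP-SMAD1/5 genes 14 rose and Rgma fell, with 16 and 1 adjusted over the list alone. Rgma (−0.58) did not pass without vehicle replicate 1 (−0.50) or vehicle replicate 2 (−0.65). The list was called by camera at adjusted p = 6.15e-41, and adjusted p = 0.00871 with an estimated correlation, the only list of this comparison to pass with that estimate. Msx2 rose by 2.47 (SE 0.18). Id1 averaged 75.6 ± 1.76 CPM with vehicle and 162 ± 13.2 CPM with BMP2, a fold change of 1.10 (SE 0.39) that did not pass the threshold (adjusted p = 0.107); without TGFβ1 replicate 1 or TGFβ1 replicate 3, whose values for Id1 lay far apart, the fold change was again 1.10 and passed, as it did with only the libraries compared (1.10), without the filter (1.11) and with the length offset (1.17). Among the 20 TGFβ-SMAD2/3 genes 8 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 6.74e-05, and adjusted p = 0.207 with an estimated correlation). The count of 12 called members was 6 without vehicle replicate 1, 5 without vehicle replicate 2 and 7 without BMP2 replicate 2. Junb rose by 2.43 (SE 0.19), Pmepa1 by 1.84 (SE 0.13) and Tgfbi by 1.72 (SE 0.13).

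Of the 17 hypertrophy genes 9 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.000108, and adjusted p = 0.0844 with an estimated correlation). Panx3 rose by 1.71 and Alpl, which encodes the alkaline phosphatase of mineralising cells, by 1.87. Mmp13, Spp1 (−1.53) and Ibsp (−1.12) were among those that fell; Spp1 shares 18.8% of its exon bases with another gene. Of the 9 osteoblast genes Alpl and Sp7 (1.31) rose and Ibsp fell, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.205 with an estimated correlation). The 24 cartilage genes went both ways, with 4 up and 4 down (6 and 5 adjusted over the list alone), a median of 0.12, a mean just under 0 and a camera adjusted p of 0.992. Without vehicle replicate 1 only 4 of them were called, and without vehicle replicate 2 only 5. Fgfr3 (1.37) and Acan were among those that rose, and Ucma (−2.19), Matn1 (−1.54) and Cilp2 (−0.94) among those that fell. Acan went from 3456 ± 175 to 5375 ± 216 CPM (0.64, SE 0.12, adjusted p = 0.00656), and did not pass without vehicle replicate 1 (0.69) or without vehicle replicate 2 (0.59). Sox9 (0.20, SE 0.15) and Col2a1 (−0.20, SE 0.13) were not shown to change. Of the 14 superficial-zone genes 5 fell, among them Prg4, Dkk3 and Vit, and 2 rose (Wif1 and Sfrp5), with 6 down and 4 up adjusted over the list alone (camera adjusted p = 0.0260, and adjusted p = 0.207 with an estimated correlation). Dkk3 fell by 2.42 (SE 0.22), and Wif1, which rose by 0.69, did not pass without vehicle replicate 2 (0.68), nor did Sfrp5 (1.31), and 4 members of the list were called without it.

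The 19 fibrous matrix genes split, with 4 up and 4 down (5 and 5 adjusted over the list alone; camera adjusted p = 0.896): Col6a2 (1.22) and Col6a1 (0.92) rose, and Dcn (−1.35) and Thbs1 (−1.24) fell. The 8 called were 4 without vehicle replicate 1, vehicle replicate 2 or BMP2 replicate 3, and 5 without BMP2 replicate 2. Of the 15 actin and contractile genes 4 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.00535, and adjusted p = 0.228 with an estimated correlation), among them Cnn2 (−1.02) and Tpm1 (−0.81). Of the 16 proteases and inhibitors 7 fell and Mmp11 (2.65) rose, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.0160, and adjusted p = 0.205 with an estimated correlation); Timp2 fell by 1.09. The 8 called were 4 without vehicle replicate 1 and 5 without vehicle replicate 2. Among 12 inflammatory mediators Ptgs2 rose, from 9.58 ± 2.72 to 121 ± 14.1 CPM, and 0 fell, the same adjusted over the list alone; the list had a median of −0.09, a mean of 0.30 and an upward camera adjusted p of 0.0506 (0.228 with an estimated correlation). Nfkbia (0.58) passed without the filter (0.60), with only the libraries compared (0.59) and without TGFβ1 replicate 1 or TGFβ1 replicate 3 (0.58 each), and Ccl5 (3.09) without the filter (3.11). Of the 18 glycolysis genes 9 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 4.53e-08, and adjusted p = 0.0844 with an estimated correlation), with Slc16a3 up by 1.51 and the glucose transporter gene Slc2a1 by 1.40. Ldha rose by 0.85, and at 0.78 did not pass without vehicle replicate 1; the 9 called were 3 without that library and 4 without vehicle replicate 2. Of the 21 oxidative phosphorylation genes 0 were called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.178).

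The third comparison sets the ligands against each other, in the fit that also holds the vehicle libraries. Cells with BMP2 held 44.2 ± 13.1 CPM of Ihh (n = 3) and cells with TGFβ1 0.226 ± 0.112 (n = 2), a log2 difference of 7.55 (SE 0.41, adjusted p = 8.41e-08). Hey1 was higher with BMP2 by 6.43 (SE 0.18) and Panx3 by 5.15 (SE 0.16). Prg4 (−5.02, SE 0.16, adjusted p = 2.18e-09) and Cilp (−5.07, SE 0.15) were lower with BMP2. In all, 3750 genes were higher and 4456 lower with BMP2, and 3623 and 3733 with the length offset. Besides Ihh, Hey1 and Panx3, the largest differences upward were those of Igkc (5.90, and 8.54 with the length offset, 532 nt), Lzts1 (5.52) and Myoc (5.20). Among the largest downward were R3hdml (−8.39), Adamtsl2 (−7.96), the growth factor gene Igf1 (−7.12), M1ap (−6.95) and Cda (−6.87). With the length offset R3hdml and Cda stood at −6.78 and −4.38.

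Of the 18 BMP-SMAD1/5 genes 15 were higher and 0 lower with BMP2, the same adjusted over the list alone (camera adjusted p = 2.77e-14, and adjusted p = 0.0772 with an estimated correlation), with Nog at 5.12, Dlx5 at 3.71, Bambi at 3.35 and Smad7 at 1.62. Id1 did not differ detectably (0.04, SE 0.38), with 1.24 and past the threshold without TGFβ1 replicate 1, −0.61 and past it without TGFβ1 replicate 3, and 2.34 with the length offset. Of the 20 TGFβ-SMAD2/3 genes 13 were lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.473 with an estimated correlation): Ltbp2 stood at −3.72 and Pmepa1 at −3.19. Superficial-zone genes were lower with BMP2 in 10 of 14 cases and higher in 3, the same adjusted over the list alone (camera adjusted p = 0.00627, and adjusted p = 0.232 with an estimated correlation). Hypertrophy genes were higher in 11 and lower in 6 of 17, the same adjusted over the list alone (camera adjusted p = 0.00627, and adjusted p = 0.232 with an estimated correlation), with Alpl at 3.29, Col10a1 at 1.44 and Mmp13 at −1.61. Osteoblast genes were higher in 5 and lower in 2 of 9, the same adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.275 with an estimated correlation), with Smpd3 at 4.52 and Sp7 at 2.11. Cartilage genes were higher in 14 and lower in 4 of 24 (15 and 5 adjusted over the list alone; camera adjusted p = 0.0893, and 0.491 with an estimated correlation), with Fgfr3 at 3.67, Sox9 at 1.60 and Acan at 1.52, and with Ucma at −5.22 (−2.82 with the length offset, 847 nt), Cilp2 at −2.90 and Chad at −2.56. Fgfr3 shares 13.9% of its exon bases with a gene on the other strand. Col2a1 did not differ detectably between the ligands (0.07, SE 0.13).

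Actin and contractile genes were lower with BMP2 in 13 of 15 and higher in 0, the same adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.407 with an estimated correlation), with Tpm1 at −2.33. Fibrous matrix genes were lower in 14 and higher in 4 of 19 (14 and 5 adjusted over the list alone; camera adjusted p = 0.0674), with Eln at −3.96 and Lox at −2.92. Of 16 proteases and inhibitors 10 were lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.229), with Htra1 at −2.59 and Adamts9 at 3.12. Ptgs2 was the only inflammatory mediator higher with BMP2 (2.25), against 10 of 12 lower, the same adjusted over the list alone (camera adjusted p = 0.0930); with the length offset 4 were lower and 2 higher. Glycolysis genes were lower in 8 and higher in 3 of 18, the same adjusted over the list alone (camera adjusted p = 0.651), with Slc16a3 at −1.23. Oxidative phosphorylation genes were lower in 9 and higher in 3 of 21, the same adjusted over the list alone (camera adjusted p = 0.136), and with the length offset lower in 6 and higher in 8; Cox4i1 stood at −4.26, and at −1.52 with the offset.

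**Figure D2:**
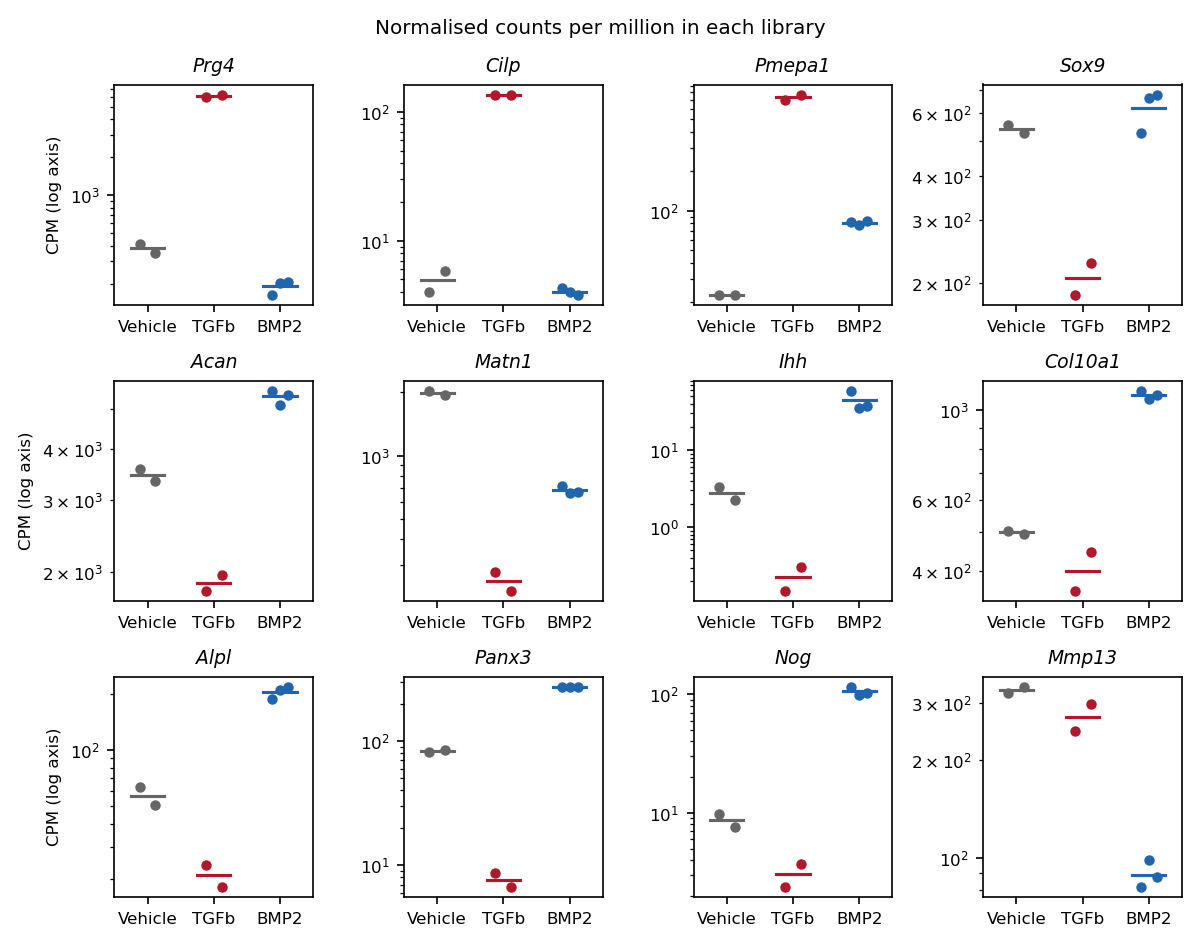
CPM (log axis) of 12 genes in each of the 7 libraries, with a line at each group's mean. Prg4, Cilp and Pmepa1 stand highest with TGFβ1, and Ihh, Nog, Panx3 and Alpl highest with BMP2.

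Both ligands were also compared gene by gene through their effects against vehicle. Of the tested genes 261 rose with both and 416 fell with both, against 216.9 and 212.2 for independent lists. A further 148 rose with TGFβ1 and fell with BMP2 (250.1 for independent lists), and 195 fell with TGFβ1 and rose with BMP2 (184.0). Pmepa1 and Slc16a3 rose with both ligands, and Matn1 and Thbs1 fell with both. Of the genes of opposite direction with a mean log2 CPM of at least 2, the largest differences between the ligands were those of Ihh (−3.56 with TGFβ1, 3.99 with BMP2), Hey1 (−3.34 and 3.09), Lzts1 (−2.29 and 3.23) and Atp6v0a4 (0.93 and −4.52). Lzts1 did not pass for TGFβ1 without vehicle replicate 2 (−1.61). The comparisons share their 2 vehicle libraries, which are too few to give each ligand its own controls: across genes the correlation of the fold changes was 0.201, whereas groups simulated without any change against the same vehicle libraries gave 0.634. Those simulations called 0.15 genes in the same direction and 0 in opposite directions on average over 20 draws. They hold no changed genes, so they cannot show how many of the shared calls come from the shared vehicle libraries. The covariance was 0.198, against 0.0863 in the simulations. The count of 677 genes of the same direction was 285 without vehicle replicate 1 and 251 without vehicle replicate 2, and the 343 were 141, 121 and, without BMP2 replicate 3, 225. With the length offset 314 genes rose with both, 385 fell with both, 152 rose with TGFβ1 and fell with BMP2, and 239 did the reverse.

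**Figure D3:**
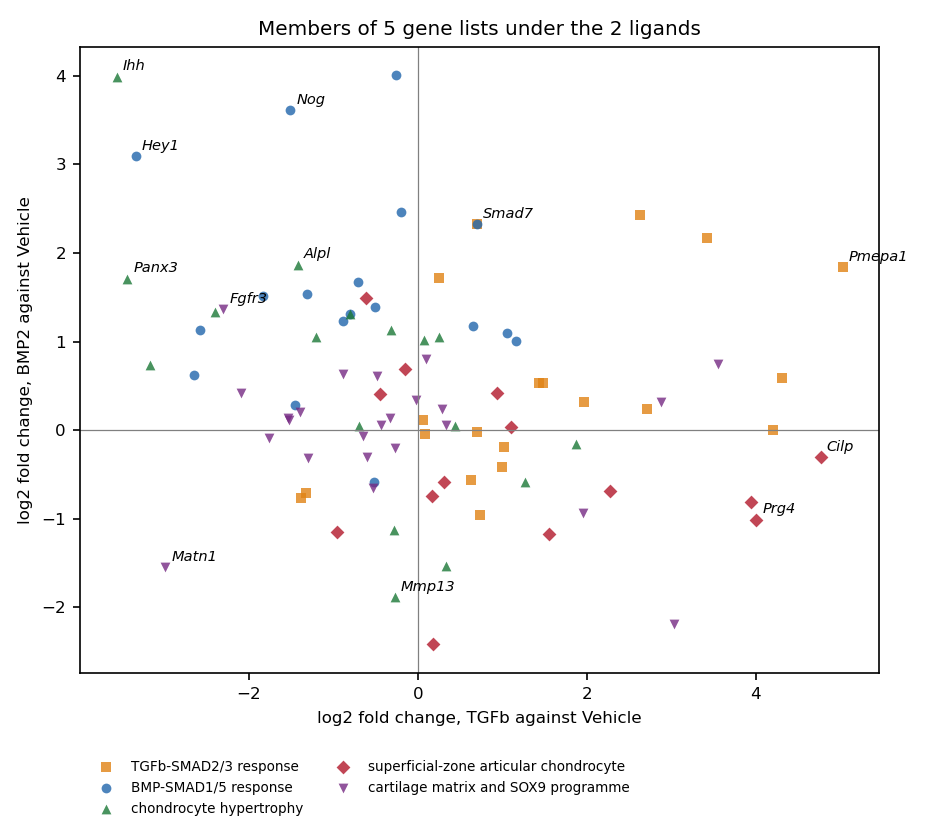
Log2 fold change against vehicle with TGFβ1 (horizontal axis) and with BMP2 (vertical axis) for the members of 5 gene lists, 1 point per gene. Ihh and Hey1 lie at −3.56 and −3.34 with TGFβ1 and at 3.99 and 3.09 with BMP2, and Prg4 lies at 4.01 and −1.01.

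Markers of other cell types were mostly low. The highest level in any library was 22.4 CPM for the leukocyte marker Lyz2, 6.52 CPM for the neutrophil marker S100a8, 3.18 CPM for the endothelial marker Egfl7, 0.598 CPM for the erythroid marker Alas2 and 10.7 CPM for the fibroblast marker Pdgfra. Higher levels were reached by Ctsk (139 CPM, osteoclast list), Cspg4 (334 CPM, pericyte list), Fabp4 (56.5 CPM, adipocyte list) and Tnnt3 (37.6 CPM, muscle list). The immunoglobulin gene Igkc, which is in none of the lists, reached 11.1 CPM in BMP2 replicate 3. With TGFβ1 the short leukocyte genes Fcer1g (674 nt) and Tyrobp (564 nt) rose by 3.33 and 3.15, and neither passed with the length offset, at 0.62 and 0.19. Pparg fell by 2.22 with TGFβ1, and the pericyte list genes Pdgfrb and Mcam rose by 0.85 and 2.33. With BMP2 Pdgfrb fell by 0.92 and Cspg4 rose by 0.69, which did not pass without vehicle replicate 2 (0.64). Pecam1 had no counts in the vehicle libraries and 1.40 ± 0.254 CPM with BMP2 (n = 3), at least 7.41-fold higher than a floor of 3 counts over the group; with TGFβ1 it had 0.376 ± 0.116 CPM (n = 2), at least 1.99-fold higher, and this call did not pass without TGFβ1 replicate 3 (adjusted p = 0.0583), vehicle replicate 1 (adjusted p = 0.0761) or vehicle replicate 2 (adjusted p = 0.0834). The floor covers counting error only.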

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

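Of the tests given here, those on transcript length and GC content and those on gene families were chosen only after the result had been seen, and those on counts thinned to equal totals were set out beforehand.

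TGFβ1 and BMP2 moved 343 genes in opposite directions against the same vehicle libraries. Of these, 148 rose with TGFβ1 and fell with BMP2, below the 250.1 for independent lists. The other 195 did the reverse, beside 184.0 for independent lists. An excess of opposite calls over independent lists is thus not shown. The shared vehicle libraries alone give positively correlated fold changes (0.634 in simulated unchanged groups), which works against opposite calls. Falling short of independent lists therefore does not argue against opposite responses. The tests below concern the genes called. With every library thinned to 6747997 counts, 295 of the 343 kept opposite calls, so most calls do not rest on the extra counts of deeper libraries. Thinning keeps each gene's expected share of its library, so it cannot test other differences that go with depth. Transcript length and GC content as the whole source are argued against, though only just past the bound set for it, since 264 of the 343 kept opposite calls with the length offset. For the genes that lost the call with the offset, length stays open, and the count is sensitive to single libraries (141 without vehicle replicate 1, 121 without vehicle replicate 2, 225 without BMP2 replicate 3). A different response to each ligand may lie behind the genes that kept it, as for Ihh (−3.69 with TGFβ1 and 4.01 with BMP2 with the offset) and Hey1 (−3.46 and 3.13), which is a hypothesis found and tested on the same data.

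Short transcripts stood higher in the TGFβ1 libraries than in the vehicle libraries. A higher total count as the source was tested by thinning. The median log2 fold change of 1070 genes with transcripts of at most 1000 nt was then 2.79 (quartiles 1.31 to 3.67). It was 2.67 in 1221 genes before. Thinning keeps each gene's expected share of its library, so this median was bound to stay near its value. The test therefore cannot decide whether the pattern goes with depth. A response of ribosomal and mitochondrial protein genes as functional groups was first tested on the 60 family members with transcripts of at least 2000 nt, whose median of 0.68 (quartiles −0.14 to 2.76), beside 3.21 in the 181 short members, fell between the bounds and left this open. A further test found a median of 2.88 (quartiles 1.55 to 3.75) in 561 short protein-coding genes outside these families and the lists, which argues against the families alone as the source of the whole pattern, and the same value is what a difference depending on length would give. Such a difference may come from how the libraries were made or from an effect of TGFβ1 on RNA that depends on length, and these cannot be told apart, since both TGFβ1 libraries and no others carry it, though not to the same degree (a median log2 difference of up to 0.35 between them within a length group).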

How the results depend on the processing

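The length offset, the restriction to transcripts of at least 2000 nt, the offset with a library left out and the lists without Snorc were chosen only after results had been seen, and the other alternatives were planned. Where a library is left out, a lone remaining sample is assumed to vary like the other groups.

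The 7517 genes changed by TGFβ1 numbered 6094 to 7894 with 1 library left out and 6457 with DESeq2. They numbered 4665 with transcripts of at least 2000 nt, where fewer genes are tested, and 4145 with a minimum fold change of 1 on the log2 scale, which is stricter by construction. The same settings gave 5311 and 4381 in place of 8206 for BMP2 against TGFβ1. The 1535 genes changed by BMP2 numbered 1233 with DESeq2, 633 with the minimum fold change, and 557 to 1698 with 1 library left out (671 without vehicle replicate 1, 981 without BMP2 replicate 3). For genes of the same direction with both ligands (677) the minimum fold change gave 207 and left-out libraries 251 to 706. For genes of opposite direction (343) these gave 97 and 121 to 455. Without a vehicle replicate 1 vehicle library remains, and beyond the fewer samples the cause was not tested. Rises made up 54.1% of the genes changed by TGFβ1, 53.9% with DESeq2 size factors and 51.3% with the length offset. For BMP2 the majority turned, from 46.4% rises to 50.5% and 51.9% in the same order.

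The replicate numbers gave no sign of pairing: deviations of the 5 pairs with the same number correlated at −0.297 to −0.0375 across 10058 genes, and 0 of the pairs reached 0.1. In a group of 2 libraries the deviations mirror each other, so these pairs are not separate checks. BMP2 replicate 1 with vehicle replicate 2 gave 0.297, and whether libraries of different number share a batch was not tested. With the replicate number as a replicate block, 771 genes changed with BMP2, 336 had the same and 158 opposite directions, and Cd34 stood at −0.11 for BMP2 against TGFβ1. Among the genes given in the text it ended the calls of Acan (0.61), Fgfr1 (−0.85), Dusp6 (−1.21), Mcm6 (0.45) and S100a9 (1.90) for BMP2, of Ctsk (0.48) and Col14a1 (1.40) for TGFβ1 and of Ngp (1.20) for BMP2 against TGFβ1. The block spends residual degrees of freedom, and whether that alone lowered the counts was not tested.

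Camera called 5 lists for TGFβ1, 11 for BMP2 and 7 for BMP2 against TGFβ1; with an estimated correlation it called 0, 1 and 0. A higher correlation between genes is argued against as the cause for lists whose estimate lay below the preset 0.01. In the tests without Snorc, the BMP-SMAD1/5 list with TGFβ1 had an estimate of 0.00764. Its unadjusted camera p still went from 0.000655 to 0.0256. The superficial-zone list, at −0.0201, went from 0.00807 to 0.0480. Since p rose for these lists too, the change from preset to estimated correlation cannot be read as correlation between genes alone. Other lists had higher estimates, and no other cause was tested. Without Snorc, which rose with TGFβ1 while most of its list fell, camera called 8 for TGFβ1. Over the 78 pairs of list and comparison, the count of called members stayed within a factor of 1.5 in 65 with the length offset and in 74 with DESeq2. It did so in 62 without vehicle replicate 1, in 58 without vehicle replicate 2 and in 69 to 74 without any 1 other library. Counts that moved are given beside many of their lists, but not beside all.

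Of the 115 genes named for TGFβ1, 114 kept direction and call with DESeq2, 115 with DESeq2 size factors and 97 with the length offset, where 10 lost the call, 1 gained it and 7 reversed. For BMP2 the same 3 settings kept 99, 105 and 101 of 105, and for BMP2 against TGFβ1 106, 107 and 91 of 107. Leaving out vehicle replicate 1 or vehicle replicate 2 ended 12 calls for BMP2 each. With the length offset, the TGFβ1 fold change reversed for S100a8 (−0.84), S100a9 (−1.72), Ngp (−0.23), Acp5 (−0.073), Pdgfra (0.25), Tnnt3 (−0.37) and Id1 (−1.17). Of these, S100a9 (adjusted p = 0.0314) and Id1 (adjusted p = 0.0087) were past the threshold in the reversed direction, and the others were not. For BMP2 against TGFβ1 the sign reversed for Ctsk (0.30), Tnnt3 (0.13) and Col2a1 (−0.016, and −0.12 with transcripts of at least 2000 nt). Ctsk for BMP2 against TGFβ1 also turned to 0.02 without a filter and to 0.0064 with only 2 groups, and spanned −0.20 to 0.062 with a library left out. Id1 spanned −0.14 to 1.71 for TGFβ1 and −0.61 to 1.24 for BMP2 against TGFβ1, set by the differing TGFβ1 replicates. Other values that changed sign with a library left out were not past the threshold in the fit reported: Tnnt3 (−0.72 to 0.36) and Mylpf (−0.97 to 0.44) for BMP2, and S100a8 (−0.85 to 0.37), Cd34 (−0.16 to 0.88) and Col2a1 (−0.062 to 0.19) for BMP2 against TGFβ1. For BMP2 against TGFβ1, S100a8 (486 nt) was past the threshold at −0.85 without BMP2 replicate 1, and at 2.69 with the length offset. The cause was not tested for these.

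With the offset and 1 library left out together, Prg4 rose with TGFβ1 in 7 of 7 fits (4.13 to 4.37) and Sox9 (−1.34 to −1.07) and Acan (−0.61 to −0.53) fell in 7 of 7. Id1 fell in 6 of 7, at −1.94 to −0.62 over the 7. All 7 fits carry the offset, so they are no separate support for this fall. In CPM neither TGFβ1 library stood clearly below vehicle for Id1 (246 and 68.3, beside 76.9 and 74.4). The offset takes off a trend over genes, and a single gene that did not share that trend would be overcorrected. Depth limits genes such as Pecam1, Ihh, Il11 and Igkc, which have few counts in a group.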

Other observations

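The values with the length offset were chosen only after the result had been seen; no other test was added here.

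With TGFβ1 4 members of the Wnt list fell and 5 rose, the same adjusted over the list alone, with a median of −0.11, a mean of 0.08 and a downward camera adjusted p of 0.219. The Wnt antagonist gene Frzb fell by 3.29 (SE 0.13), from 124 ± 5.58 to 12.7 ± 1.02 CPM, and Wnt5a by 2.42 (SE 0.17). With BMP2 7 of 20 rose and 4 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.178; 4 called in all without vehicle replicate 2), with Wnt11 up by 2.21 (SE 0.23), Nkd1 by 1.21 and Notum by 3.23 (SE 0.47); Notum shares 29.4% of its exon bases with a gene on the other strand. BMP2 against TGFβ1 gave 8 higher and 5 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.0893).

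Of 8 tested Notch genes TGFβ1 lowered 3 and raised 2, the same adjusted over the list alone (camera adjusted p = 0.171). Notch1 fell by 2.35 (SE 0.19) and the ligand gene Jag1 rose by 1.97 (SE 0.24). With BMP2 Hey1 rose and 0 fell (2 and 1 adjusted over the list alone), and camera called the list at adjusted p = 0.00470, against 0.207 with an estimated correlation. Hes1 (1.74) passed without the filter (1.76), BMP2 replicate 1 (0.73) or BMP2 replicate 2 (2.05), and Notch2 (−0.39) without TGFβ1 replicate 1 or TGFβ1 replicate 3 (−0.39 each), with only the libraries compared (−0.39) and with transcripts of at least 2000 nt (−0.38). BMP2 against TGFβ1 gave 5 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0241, and 0.407 with an estimated correlation).

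Of 14 FGF and ERK feedback genes TGFβ1 lowered 6 and raised 2, the same adjusted over the list alone (camera adjusted p = 0.171; 5 called in all without vehicle replicate 2). Fgfr3 fell by 2.30 (SE 0.19), and the metabolic hormone gene Fgf21 rose by 4.06, and by 1.93 with the length offset (951 nt); it stood at 338 CPM in TGFβ1 replicate 1 and 106 CPM in TGFβ1 replicate 3. With BMP2 Fgf2 (0.84) and Fgfr3 rose and Fgfr1 (−0.86) and Dusp6 (−1.15) fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.441). Fgf2 did not pass without vehicle replicate 2 (0.74). Neither Fgfr1 nor Dusp6 passed without vehicle replicate 1 (−0.93 and −0.94), vehicle replicate 2 (−0.77 and −1.34) or BMP2 replicate 3 (−0.73 and −1.17), nor did Fgfr1 without BMP2 replicate 2 (−0.72) or Dusp6 without BMP2 replicate 1 (−0.94) or with DESeq2 (−1.12). BMP2 against TGFβ1 gave 5 higher and 3 lower, the same adjusted over the list alone, with a median of 0.34, a mean of −0.04 and an upward camera adjusted p of 0.306.

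Of 20 cell cycle genes TGFβ1 raised 8 and lowered 6 (9 and 6 adjusted over the list alone; camera adjusted p = 0.998; 8 called in all without vehicle replicate 1). Tyms rose by 2.28 (129 CPM in TGFβ1 replicate 1 and 67.6 CPM in TGFβ1 replicate 3) and Mcm5 by 1.12. Birc5, of 947 nt, rose by 2.41 and did not pass with the length offset (0.40; 199 CPM in TGFβ1 replicate 1 and 92.2 CPM in TGFβ1 replicate 3), and Mki67, of 10061 nt, fell by 0.64 and did not pass with it (−0.01). With BMP2 Rrm2 (0.80) and Mcm6 (0.43) rose and 0 fell, the same adjusted over the list alone, with camera adjusted p = 0.0453 and 0.320 with an estimated correlation. Rrm2 did not pass without vehicle replicate 1 (0.73) or vehicle replicate 2 (0.89), and Mcm6 did not pass without any one of the vehicle or BMP2 libraries: vehicle replicate 1 (0.38), vehicle replicate 2 (0.48), BMP2 replicate 1 (0.38), BMP2 replicate 2 (0.41) and BMP2 replicate 3 (0.49). BMP2 against TGFβ1 gave 10 higher and 8 lower, the same adjusted over the list alone, with a median of 0.19, a mean of −0.10 and an upward camera adjusted p of 0.476.

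Of 26 superfamily ligands, receptors and antagonists TGFβ1 raised 7 and lowered 12 (7 and 13 adjusted over the list alone; camera adjusted p = 0.429). The activin subunit gene Inhba rose by 4.15 (SE 0.21), the BMP antagonist gene Chrdl2 by 3.99 (SE 0.16) and Bmp7 by 2.05, and Chrdl1 fell by 1.35. BMP2 raised 5 and lowered 6 (7 and 7 adjusted over the list alone), with a median of −0.10, a mean of 0.02 and an upward camera adjusted p of 0.896; 6 were called in all without vehicle replicate 1 and 5 without vehicle replicate 2. The antagonist gene Grem1 rose by 1.67 and Tgfbr3 (−1.94) and Tgfb2 (−1.07) fell. BMP2 against TGFβ1 gave 11 higher and 9 lower (11 and 11 adjusted over the list alone; camera adjusted p = 0.463).

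Of 17 genes of proteoglycan and hyaluronan synthesis TGFβ1 raised 7 and lowered 5 (7 and 6 adjusted over the list alone), with a median of −0.17, a mean of 0.22 and a downward camera adjusted p of 0.655. Chst3 rose by 2.21 and Hs6st2 (−1.90), Csgalnact1 (−1.50) and the sulfate transporter gene Slc26a2 (−1.21, and −0.61 with the length offset) fell. BMP2 raised 4 and lowered 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.119), with Ugdh up by 0.96 (SE 0.12). The 6 called were 1 without vehicle replicate 1, 2 without vehicle replicate 2 or BMP2 replicate 3, and 3 without BMP2 replicate 2. BMP2 against TGFβ1 gave 10 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.299), with Slc26a2 at 1.65 and Has1 at −4.73.

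Among the marker lists, leukocyte genes gave 4 higher and 2 lower of 9 with TGFβ1 (camera adjusted p = 0.616), 0 with BMP2 (0.109; 0 at an adjusted p over the list alone) and 1 higher and 6 lower for BMP2 against TGFβ1 (0.229). With the length offset TGFβ1 raised 0 and lowered 3 of them, 3 were called without vehicle replicate 2, and for BMP2 against TGFβ1 4 were called without TGFβ1 replicate 1. Lyz2 with BMP2 (−0.80, adjusted p = 0.0513) passed with DESeq2 (−0.77), without the filter (−0.79), with only the libraries compared (−0.80), with the length offset (−0.82), without TGFβ1 replicate 1 or TGFβ1 replicate 3 (−0.80 each) and without vehicle replicate 1 (−1.10). Mrc1 (−2.65) did not pass for TGFβ1 without TGFβ1 replicate 1 (−2.61) or vehicle replicate 2 (−1.76). Neutrophil genes gave 1 higher of 3 with each ligand (camera adjusted p = 0.848 with TGFβ1, and 0.0415 with BMP2, 0.207 with an estimated correlation) and 1 higher for BMP2 against TGFβ1 (0.525); adjusted over the list alone these were 0, 3 and 0, and the levels reached 6.52 CPM. S100a8 (486 nt) with TGFβ1 (1.95) turned to −0.84 with the length offset, which did not pass. It also did not pass without TGFβ1 replicate 1 (1.67), vehicle replicate 1 (1.79) or vehicle replicate 2 (2.08), nor did S100a9 with BMP2 (1.91) without BMP2 replicate 1 (1.51), BMP2 replicate 3 (2.04), vehicle replicate 1 (1.84) or vehicle replicate 2 (2.00), or with DESeq2 (1.93). Ngp for BMP2 against TGFβ1 (1.27) did not pass without either TGFβ1 library (1.69 without replicate 1, 0.96 without replicate 3) or either vehicle library (1.32 and 1.28), nor with DESeq2 or without the filter (1.34 each), and was at 2.20 past the threshold with the length offset. S100a8 (2.69) and S100a9 (3.51, 519 nt) were also past the threshold with the length offset for BMP2 against TGFβ1, so all 3 genes were higher there. Without BMP2 replicate 2 the neutrophil list had 2 genes called for BMP2, and for BMP2 against TGFβ1 2 without BMP2 replicate 1 and 0 without BMP2 replicate 3. Osteoclast genes gave 1 higher of 2 with TGFβ1 (0.848; Ctsk at 0.42, not past the threshold at 0.32 to 0.47 without BMP2 replicate 2, either TGFβ1 library or either vehicle library, nor at 0.42 with DESeq2, 0.37 without the filter or 0.076 with the length offset), 0 with BMP2 (a median of −0.14 with an upward camera adjusted p of 0.979) and 1 lower for BMP2 against TGFβ1 (0.736). With the length offset Acp5 of the osteoclast list no longer passed for BMP2 against TGFβ1 (−0.56). Endothelial genes gave 1 higher of 2 with TGFβ1 (a downward camera adjusted p of 0.998), with BMP2 (0.0965) and for BMP2 against TGFβ1 (0.448, with Pecam1 at 1.85, and 1.57 without TGFβ1 replicate 1, which did not pass). Egfl7 fell past the threshold with TGFβ1 only with the length offset, at −1.15. Fibroblast genes gave 1 higher of 4 with TGFβ1 (Col14a1 at 1.54, and 1.17 without vehicle replicate 2, which did not pass; 2 called without TGFβ1 replicate 1; a median of 0.17 with a downward camera adjusted p of 0.998), 0 with BMP2 (0.119; 2 lower adjusted over the list alone) and 2 lower for BMP2 against TGFβ1 (0.555). Adipocyte genes gave 1 higher and 1 lower of 2 with TGFβ1 (a median of 0.41 with a downward camera adjusted p of 0.848), 0 with BMP2 (0.119; 1 higher adjusted over the list alone; Fabp4 at 1.14 passed at 1.18 with DESeq2, 1.15 without the filter, 1.42 without BMP2 replicate 1 and 1.12 with the length offset) and 1 each way for BMP2 against TGFβ1 (0.463). Muscle genes gave 2 higher of 2 with TGFβ1 (0.309, and 0 with the length offset), 0 with BMP2 (0.750) and 2 lower for BMP2 against TGFβ1 (0.236). For BMP2 against TGFβ1 Tnnt3 reversed direction with the length offset, so the 2 did not both stay lower. Pericyte genes gave 4 higher of 4 with TGFβ1 (0.171), 1 each way with BMP2 (0.373; 1 called in all without vehicle replicate 2) and 3 lower for BMP2 against TGFβ1 (0.0940). Adjusted over the list alone, the counts for these lists were the same but for osteoclast genes with TGFβ1 (2 higher) and endothelial genes for BMP2 against TGFβ1 (2 higher), besides those already given.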
